A study of Homo sapiens with 4 samples.

How the data were processed

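The series holds 4 RNA-seq libraries of Huh7 cells, 1 for each of shControl with DMSO, shControl with rapamycin, shARID1A with DMSO and shARID1A with rapamycin (100 nM for 6 hours). Per the labels' protocols, total RNA was extracted with TRIZOL and libraries were prepared with standard Illumina protocols. Per the submitters' processing notes, reads were aligned with BWA (version not given) to GRCh38/hg38. Each library has a file of genes with FPKM values, deposited by the authors and named as FPKM per the file headers. The counting tool, the annotation, the strand setting and the replicate handling are not given in the sources used here. The files list 19932 gene names, of which 27 had been turned into dates and 2 were listed more than 1 time, and 19905 (99.9%) matched GENCODE release 29, the source of the GRCh38 coordinates printed here. Symbols are given as in the files.

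The FPKM values of a gene were whole multiples of a step, so that the fragments behind them could be recovered. The step of each gene and the relative depth of the libraries (1 : 0.857 : 1.5 : 1.07 in the order above) were found from the low genes, and the library totals are those at which the steps correspond to lengths in whole bases. The values of recovered genes are whole at a tolerance of 0.01 by construction, and these genes hold 98.5% of all values above 0. Fragments were recovered for 15539 of 16459 genes above 0 in at least 1 library (94.4%), and 676 genes needed a common factor taken from the others. Another 920 genes were above 0 in 1 library only, and their fragments are not determined. Library totals came out at 21465499, 18391358, 32253417 and 22920281 fragments, and the recovered genes held 98.4% of each. A ratio of FPKM between libraries equals the ratio of fragments per 1000000 fragments of the library (fpm). The lengths in the FPKM mostly differed from the exonic lengths of the genes that carry them. Across 10868 genes with at least 50 fragments in each library the Spearman correlation of that length with the gene's own exonic length was -0.016, and ALB, AFP and FLNA had lengths of 108, 119 and 96 bases. Apart from the Pearson r between whole libraries on log2(FPKM + 1), no result therefore compares FPKM levels between genes. Ratios of a gene between libraries do not depend on the length. The floors of FPKM in the main rule do depend on it, so that which genes pass them rests in part on these lengths. On log2(FPKM + 1), the pseudocount weighs more on a gene whose length in the FPKM is long. FBL, HSPA1A, HSPA1B, SESN2 and PCK2 are listed at 0 in every library and were read as listed at 0 only.

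The tests, gene lists, named-gene rule and the first set of other settings were written down before the data were examined. That plan had a branch for counts and a branch for FPKM, and the FPKM branch gave the main results. With 1 library per group no p-value is given for a comparison of 2 libraries, and the main counts rest on a rule of size. The only models with p-values are the additive ones named below, which take the difference of the rapamycin effects as error. A gene counted as higher or lower when log2(FPKM + 1) differed at least 2-fold and the higher value was at least 1, among 10788 genes with a mean FPKM of at least 1, with scaling as deposited. This was done for shARID1A against shControl in each treatment, rapamycin against DMSO in each genotype, both pairs of comparisons together, and the difference of the rapamycin effects. Log2 changes on this scale understate the change of low genes. The number shared by 2 comparisons was set beside n1 x n2 / N for independent lists. Intervals of fpm are exact Poisson intervals and intervals of ratios exact conditional binomial intervals at 95%. The interval of a difference of effects comes from the 4 counting errors. All cover counting error only, since reads without molecular identifiers are not independent molecules. Correlations across genes were set beside 20 simulated sets of libraries with counting error only, and genes are not independent replicates.

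The gene lists covered SWI/SNF subunits, YAP/TAZ targets, ATF4 targets, sterol synthesis, fatty acid synthesis, glycolysis and hypoxia response, lysosome, autophagy, cytosolic ribosomal proteins, ribosome biogenesis, G1/S and replication, G2/M and mitosis, p53 targets, immediate early genes, hepatocyte function, fetal liver and biliary markers, extracellular matrix, interferon-stimulated genes, NF-kB, unfolded protein response, NRF2 targets, respiratory chain, insulin and FOXO feedback, mTOR components, Wnt targets, heat shock, markers of 5 other cell types, and mitochondrially encoded, replication histone and small non-coding RNA genes. A list's median log2 change was placed among 10000 random lists of the same size matched on mean fpm in 20 bins, as a description of these libraries. As deposited, the median log2 change of all genes was 0.069 for the knockdown with DMSO, -0.015 with rapamycin, 0.059 for rapamycin in shControl and -0.027 in shARID1A, so that centring moves small list medians by as much, while the random lists share the shift. Lists with under 5 measured genes got no percentile.

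Named genes followed a rule. For the knockdown over both treatments and for rapamycin over both genotypes these were up to 13 higher and 13 lower genes with the largest smaller change. Each single comparison gave its 5 highest and 5 lowest, the difference of effects its 8 and 8, and each list up to 4 members with the largest main effect and a member opposing its list, and any SWI/SNF subunit could be named. Many genes so ranked had few fragments, and the text names those with the clearer values. Some single genes are not reported here. As an alternative chosen after seeing the data, the rule that the plan gave for counts was applied to the recovered fragments (mean of at least 10, prior of 0.5, 2-fold, interval excluding 1, 12873 genes), with the same naming rule and at least 50 fragments on the higher side. List members with the largest difference of rapamycin effects, the most abundant genes, and the genes of the closing part on other observations that no list holds were chosen after their values were seen.

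Of the other settings, those fixed first were centring at the median, quantile normalization, no filter, a mean FPKM of at least 5, a pseudocount of 0.1, a 1.5-fold rule, leaving out mitochondrial and histone genes, the mean of a list, and an additive limma model of genotype and treatment with 1 residual degree of freedom. Count models and the scalings that go with them were not run, because the deposited values are FPKM. Added later were the recovered fragments, limma-voom on them, and genes with a mean of at least 500 fragments. The scripts were tested on simulated libraries with seeded changes. Fragments were recovered for 96.7% of 15316 simulated genes. For shARID1A against shControl over both treatments, genes seeded at 2-fold were called in 2% by the FPKM rule and 26% by the fragment rule, and those seeded at 4-fold in 94% and 100%, with 1 and 0 unchanged genes called. In the single DMSO comparison 13 of 10772 and 29 of 12851 simulated genes were called, which gives the scale of calls from counting error. Of 200 lists of 20 unchanged genes drawn at random, 4% fell outside the central 95%. This checks the calculation only, since members of a real list may vary together. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.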

Results

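RNA-seq measured total RNA of Huh7 cells, an established line of human hepatocellular carcinoma. The cells carried a control short hairpin RNA (shControl) or a hairpin against ARID1A (shARID1A), the gene of a subunit of the SWI/SNF chromatin remodelling complex. Cells of both kinds were kept with the solvent DMSO or given 100 nM rapamycin, an inhibitor of the kinase complex mTORC1, for 6 hours. The 4 groups held 1 library each, so that no value has a replicate and no difference below has a replicate check. The libraries held 21465499 fragments (shControl with DMSO), 18391358 (shControl with rapamycin), 32253417 (shARID1A with DMSO) and 22920281 (shARID1A with rapamycin). Of 19932 listed genes, 15307, 15122, 15561 and 15225 were above 0 in these libraries. Levels are fragments per 1000000 fragments of the library (fpm), and ratios are ratios of fpm between 2 libraries. The 95% intervals are exact, cover counting error only, and compare those libraries, not the conditions. "Beyond counting error" means that this interval of the ratio excludes 1. Counts of list members beyond counting error use ratios as deposited, without centring, and are given without the share over all genes. The 10 most abundant genes took 8.88% of the fragments, among them MT-CO1 (mean 21954 fpm), the fibronectin gene FN1 (9263 fpm) and the alpha-fetoprotein gene AFP (4400 fpm).

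ARID1A itself (chromosome 1, 26693236 to 26782110, GRCh38) was lower in both shARID1A libraries than in either shControl library. Its level was 197 fpm (interval 191 to 203) in shControl with DMSO and 175 fpm (170 to 180) in shARID1A with DMSO. With rapamycin it was 224 fpm (217 to 231) in shControl and 156 fpm (151 to 161) in shARID1A. The ratio of shARID1A to shControl was thus 0.890 (0.855 to 0.926) with DMSO and 0.695 (0.665 to 0.727) with rapamycin. Over 7439 genes with a mean of at least 500 fragments, the log2 changes had an SD of 0.293 with DMSO and 0.289 with rapamycin. The log2 change of ARID1A lay inside that SD with DMSO and beyond it with rapamycin. Of 24 measured SWI/SNF subunit genes, 10 were higher and 3, ARID1A among them, lower in shARID1A beyond counting error in both treatments. SMARCC1 had ratios of 1.40 with DMSO and 1.42 with rapamycin, SMARCC2 1.3 and 1.44, and BCL7B 1.61 and 1.52. The ATPase gene SMARCA4 had ratios of 1.29 and 1.28, and ARID1B, the paralogue of ARID1A, 1.25 and 1.3. The median log2 change of the list, averaged over both treatments, was 0.13, at percentile 98.0 of 10000 random lists of the same size matched on mean expression, while the single treatments lay inside the central 95%, at percentiles 95.3 with DMSO and 96.9 with rapamycin.

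**Figure D1:**
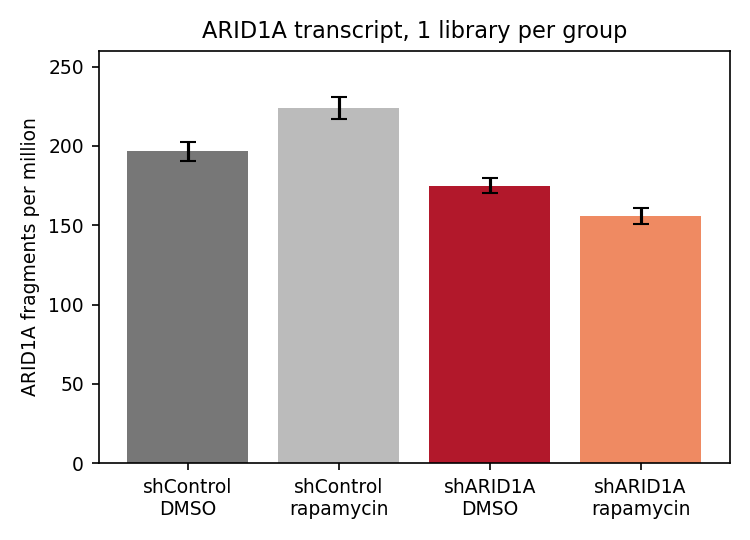
ARID1A level in fpm in the 4 libraries, 1 per group, with 95% counting intervals. Both shARID1A libraries, at 175 and 156 fpm, lie below both shControl libraries, at 197 and 224 fpm.

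With DMSO, the comparison of shARID1A with shControl shows which transcripts differed with the hairpin alone. The collagen gene COL3A1 was higher in shARID1A, with a ratio of 3.76 (2.5 to 5.83), and the zinc finger gene ZNF114 lower, at 0.162 (0.126 to 0.206). The cytokine gene CSF3 had a ratio of 0.194 (0.104 to 0.343) and the lymphangiogenic factor gene CCBE1 0.283 (0.222 to 0.357). Genes of insulin and FOXO feedback had a median log2 change of -0.53 (percentile 0), with 10 of 13 members lower and 1 higher beyond counting error. Among them CCNG2 had a ratio of 0.391, KLF15 0.392, TXNIP 0.439 and IRS2, which encodes an adaptor of the insulin receptor, 0.446. Fatty acid synthesis genes had a median of -0.30 (percentile 0), with 7 of 13 members lower and 4 higher beyond counting error, among the lower ELOVL6 at 0.586, FADS1 at 0.596 and ACLY at 0.614. Sterol genes had a median of -0.17 (percentile 0.01), with IDI1 at 0.581. With rapamycin both lists lay inside the central 95% of random lists, with medians of 0.02 (percentile 63.2) for fatty acid synthesis and 0.006 (percentile 53.7) for sterol genes. Insulin and FOXO genes had a median of 0.10 with rapamycin (percentile 94.4), with 8 of 13 members higher and 3 lower beyond counting error. Ribosome biogenesis genes were higher with DMSO, with a median of 0.37 (percentile 100) and 26 of 28 members higher beyond counting error. POLR1C had a ratio of 1.72, NOP16 1.67 and RRP12 1.57, against 0.472 for RRP9. With rapamycin the median of this list was 0.08 (percentile 96.95), inside the central 95%. Mitochondrially encoded transcripts took 9.17% of the fragments in shControl with DMSO and 7.78% in shARID1A with DMSO. At 2-fold on log2(FPKM + 1), 27 of 10788 genes were higher and 51 lower, of which 11 and 16 had under 50 fragments in every library. Centring each pair of libraries at its median gave 20 and 70, and the same 2-fold rule on fragments gave 137 and 211 of 12873 genes.

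With rapamycin, the same comparison shows which transcripts differed with the hairpin in cells under mTORC1 inhibitor. The integrin gene ITGB5 was higher in shARID1A, with a ratio of 4.12 (3.87 to 4.38), as was the survivin gene BIRC5, at 3.34 (3.10 to 3.61). The growth factor gene FGF2 had a ratio of 4.16 (2.16 to 8.79). CHAC1, whose product degrades glutathione, was lower at 0.242 (0.148 to 0.382), and the sodium pump subunit gene ATP1B2 at 0.195 (0.105 to 0.340). YAP/TAZ target genes had a median log2 change of 0.26 (percentile 100), and 16 of 21 were higher and 2 lower beyond counting error. CYR61 had a ratio of 3.36 (3.16 to 3.58), CTGF 3.06 (2.93 to 3.18) and ASAP1 2.66 (2.48 to 2.85), with GADD45A at 0.685 as an exception. NF-kB inflammatory genes had a median of 0.16 (percentile 99.8) and lysosome genes 0.10 (percentile 99.3). With DMSO both of these lists went the other way, with medians of -0.21 (percentile 0.02) and -0.16 (percentile 0). At 2-fold with rapamycin, 45 of 10788 genes were higher and 57 lower. Of these, 19 and 26 had under 50 fragments in every library, and the rule on fragments gave 135 and 219.

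Over both treatments, the genes that differed in the same direction gave a difference between shARID1A and shControl cells seen in 2 pairs that share no library. Both pairs compare the same 2 kinds of cells. Lower ARID1A and any other difference between these cells therefore cannot be told apart, and the independent lists and simulations below do not separate them. HABP4, an RNA-binding protein gene (chromosome 9, 96450201 to 96491336), was higher in shARID1A with ratios of 2.45 (2.28 to 2.64) with DMSO and 2.33 (2.15 to 2.53) with rapamycin. NOLC1, a nucleolar phosphoprotein gene, had ratios of 2.61 (2.48 to 2.75) and 2.11. Among less abundant genes, ZNF616 had ratios of 3.16 and 2.69, BBOX1, of carnitine synthesis, 4.53 and 2.60, TBX15 2.43 and 4.30, and the axonemal dynein gene DNAH7 5.55 (2.38 to 15.8) and 5.42 (1.89 to 21.3). Lower in shARID1A were METRNL, at 0.103 (0.0493 to 0.196) and 0.0892, the pentraxin gene PTX3, at 0.248 and 0.158, and the prostaglandin transporter gene SLCO2A1, at 0.377 and 0.327. The coagulation factor gene F5 had ratios of 0.410 and 0.366, the phosphatase gene DUSP5 0.413 and 0.357, and SSR2, of the translocon-associated complex, 0.418 and 0.426. FKBP1A, whose product FKBP12 is the protein that binds rapamycin, had ratios of 0.512 (0.492 to 0.532) and 0.462 (0.442 to 0.483), and MTOR 0.757 and 0.726. Their list went the other way in number, with 9 of 30 mTOR pathway components higher and 2 lower beyond counting error in both treatments. At 2-fold, 7 genes were higher and 17 lower in both treatments, where independent lists would share 0.113 and 0.269, and 1 and 2 genes went in opposite directions. The rule on fragments gave 21 higher and 63 lower, against 1.44 and 3.59 for independent lists. Across 10788 genes, which are not independent replicates, the changes in both treatments had a Pearson r of 0.456 and a Spearman rho of 0.448, against a mean r of 0.00373 in 20 simulations with counting error only.

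Of the gene lists, glycolysis and the hypoxia response differed most steadily with the hairpin. Its 22 measured genes had a median log2 change of -0.48 with DMSO and -0.41 with rapamycin, percentile 0 in both, and 15 were lower and 0 higher beyond counting error in both treatments. LDHA, the lactate dehydrogenase gene, had ratios of 0.598 (0.587 to 0.610) and 0.631 (0.617 to 0.645), the lactate exporter gene SLC16A3 0.626 and 0.525, and the pyruvate dehydrogenase kinase gene PDK1 0.552 and 0.650. PFKFB4, of the control of glycolysis, had ratios of 0.413 (0.363 to 0.470) and 0.268 (0.227 to 0.315). Genes of G2/M and mitosis had medians of -0.09 (percentile 0.18) and -0.23 (percentile 0), with 10 lower and 3 higher in both treatments, such as KIF23 at 0.652 and 0.655, but CDC20 was higher at 1.08 and 2.59. NRF2 target genes had medians of -0.18 (percentile 0.16) and -0.11 (percentile 2.20), with 6 lower and 0 higher in both treatments, such as AKR1B10 at 0.673 and 0.561. YAP/TAZ targets had a median of 0.15 (percentile 91.1) with DMSO beside 0.26 with rapamycin, with 10 higher and 1 lower in both. Hepatocyte function genes had medians of 0.15 (percentile 97.7), which was 0.08 after centring, and 0.02 (percentile 66.4), and as the mean of the list their change over both treatments lay inside the central 95%, at percentile 97.0. HP, the haptoglobin gene, had ratios of 1.95 and 1.45, and APOH 1.35 and 1.59, whereas CEBPA had 0.695 and 0.699. p53 target genes had medians of -0.17 (percentile 0.03) and -0.08 (percentile 14.3), and ATF4 target genes -0.04 (percentile 2.54) and -0.07 (percentile 11.3).

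**Figure D2:**
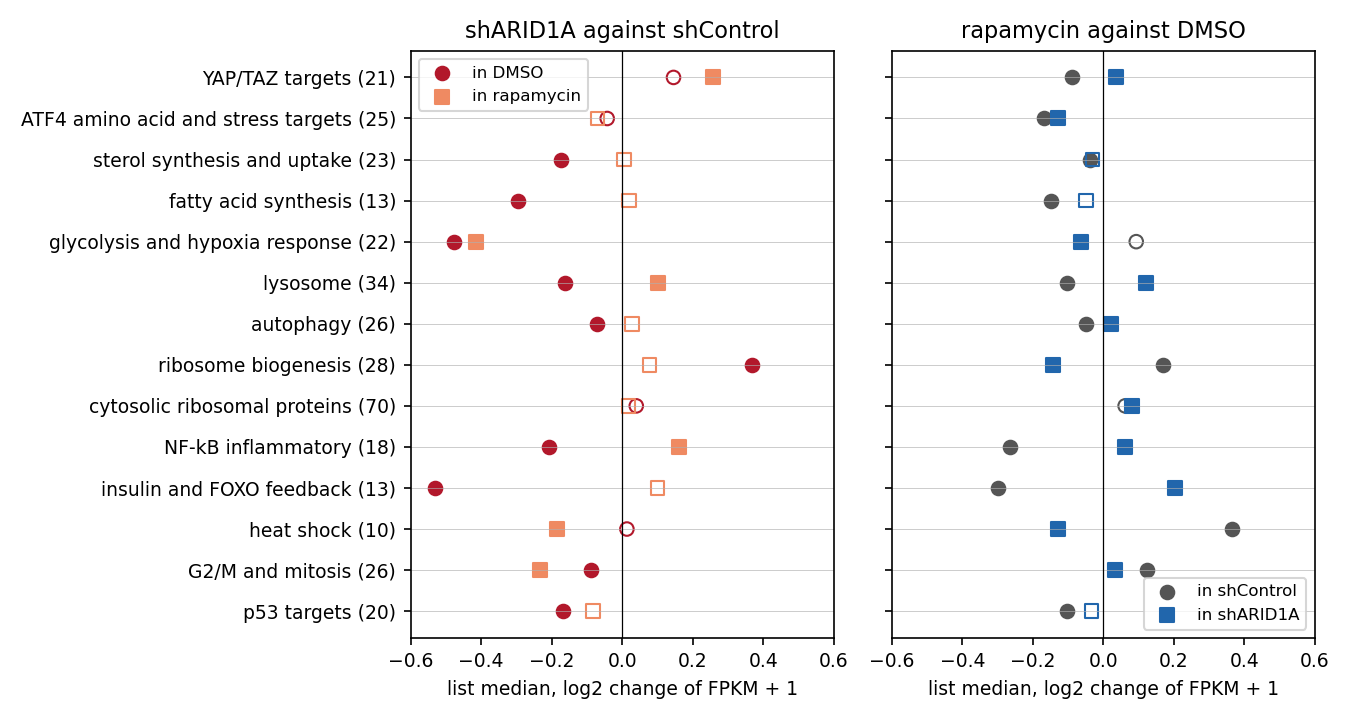
Median log2 change of FPKM + 1 for 14 gene lists with the number of measured genes in brackets, shARID1A against shControl on the left and rapamycin against DMSO on the right, 1 library per group. Filled symbols lie outside the central 95% of 10000 matched random lists, and the glycolysis list lies at -0.48 and -0.41 on the left.

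In shControl cells, the comparison of rapamycin with DMSO shows which transcripts differed after 6 hours with the inhibitor. Of the ATF4 target genes, PSAT1, of serine synthesis (chromosome 9, 78297143 to 78330093), had a ratio of 0.341 (0.330 to 0.353), MTHFD2 0.491 (0.446 to 0.539), SHMT2 0.505 (0.490 to 0.521) and PSPH 0.530 (0.481 to 0.583). KLHL24, a gene of the ubiquitin system, was at 0.3 (0.278 to 0.324), the mTORC1 activator gene RHEBL1 at 0.328 (0.206 to 0.508) and the gluconeogenesis gene FBP1 at 0.324 (0.170 to 0.583). The nuclear receptor gene NR0B2 was higher at 2.76 (1.58 to 5.0), as were FOSL1 at 2.27 (1.6 to 3.24) and CHAC1, itself an ATF4 target gene, at 2.25 (1.54 to 3.34). ATF4 target genes had a median log2 change of -0.17 (percentile 0), with 15 of 25 lower and 2 higher beyond counting error. Insulin and FOXO feedback genes had a median of -0.30 (percentile 0, 10 of 13 lower and 0 higher), NF-kB genes -0.26 (percentile 0, 15 of 18 lower and 0 higher) and fatty acid synthesis genes -0.15 (percentile 0.01). Lysosome genes had a median of -0.10 (percentile 0), with 22 of 34 lower and 1 higher. Sterol genes had a median of -0.04 (percentile 0.27), with SC5D at 0.581. Heat shock genes had a median of 0.37 (percentile 100), led by DNAJB1 at 1.53, although HSPA4 was at 0.627 and HSPD1 at 0.632. Mitochondrially encoded transcripts took 9.17% of the fragments with DMSO and 7.96% with rapamycin. At 2-fold, 13 of 10788 genes were higher and 33 lower, with 12 and 18 of them under 50 fragments in every library. The rule on fragments gave 48 and 81, with 3 and 17 genes in both rules.

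In shARID1A cells, the same 4 ATF4 target genes were again lower with rapamycin, while several of the genes lower in shControl were higher. PSAT1 had a ratio of 0.576 (0.556 to 0.597), PSPH 0.637, SHMT2 0.671 and MTHFD2 0.765. KLHL24 was higher, at 2.70 (2.55 to 2.85), as were RHEBL1 at 2.30 (1.70 to 3.13), TMPRSS7 at 3.03 (1.87 to 5.03) and CSF3 at 2.81 (1.5 to 5.49). CHAC1 was lower at 0.263 (0.164 to 0.405) and M6PR, the gene of a receptor that sorts enzymes to lysosomes, at 0.409 (0.381 to 0.437). ATF4 target genes had a median of -0.13 (percentile 0), with 14 of 25 lower and 1 higher. Lysosome genes had a median of 0.12 (percentile 100), with 20 of 34 higher and 1 lower, and insulin and FOXO feedback genes 0.20 (percentile 100), with 8 of 13 higher and 1 lower. Ribosome biogenesis genes had a median of -0.14 (percentile 0), with 18 of 28 lower and 1 higher. At 2-fold, 9 of 10788 genes were higher and 10 lower, with 6 and 8 of them under 50 fragments in every library. The rule on fragments gave 40 and 68, with 4 and 3 genes in both rules.

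Across both genotypes, rapamycin was accompanied by lower ATF4 target transcripts. Of 25 ATF4 target genes, 7 were lower and 0 higher beyond counting error in both genotypes, PSAT1, SHMT2, PSPH and MTHFD2 among them. The size of the change was not alike in both. The list's median difference of the rapamycin effects was 0.10 (percentile 99.98), or 0.182 after centring. The difference lay above 0 for 11 and below 0 for 6 of the 25 genes beyond counting error. The endoplasmic reticulum gene EDEM1 had ratios of 0.602 (0.573 to 0.631) in shControl and 0.625 (0.592 to 0.659) in shARID1A, M6PR 0.625 and 0.409, SC5D 0.581 and 0.709, and ME1, the malic enzyme gene, 0.574 and 0.744. Cytosolic ribosomal protein genes had medians of 0.06 (percentile 93.9, inside the central 95%) in shControl, which was 0.005 after centring, and 0.08 (percentile 100) in shARID1A. As deposited, 36 of 70 were higher and 0 lower in both genotypes, such as RPS29 at 1.1 and 1.13. The count for shControl includes the shift of all genes, whose median log2 change was 0.059 in shControl and -0.027 in shARID1A. Nuclear-encoded respiratory chain genes had medians of 0.12 (percentile 99.5) and 0.04 (percentile 99.7), with 8 of 35 higher and 0 lower in both. At 2-fold on log2(FPKM + 1), ST14 was the 1 gene higher and AC126755.2 the 1 gene lower in both genotypes, each with under 50 fragments in every library, where independent lists would share 0.0108 and 0.0306. Centring at the median and quantile normalization each left 0 genes higher, and the rule on fragments gave 0 higher and 3 lower.

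The crossed design asks whether the rapamycin response differed between genotypes, and for the genes and lists below it had opposite directions. KLHL24 was lower with rapamycin in shControl and higher in shARID1A, a difference of 3.17 on the log2 scale of fragments (3.03 to 3.30). The same held for CREBRF, a transcription regulator gene, with ratios of 0.393 and 2.04, for MNT, of a MYC antagonist, with 0.386 and 1.81, and for FBXO32, of a ubiquitin ligase, with 0.471 and 2.23. IRS2 had ratios of 0.504 and 1.6, CCNG2 0.594 and 1.78 and ITGB5 0.366 and 1.24. CHAC1 had the reverse order with 2.25 and 0.263, as did RGS2, of a G protein regulator, with 2.23 and 0.631, and DNAJB1 with 1.53 and 0.712. Of 34 lysosome genes, 18 were lower in shControl and higher in shARID1A beyond counting error and 1 the reverse, with a median difference of 0.23 (percentile 100). RRAGC had ratios of 0.493 (0.459 to 0.528) and 1.71 (1.62 to 1.81), FLCN 0.601 and 1.58, and FNIP1 0.614 and 1.40, 3 genes of amino acid sensing at the lysosome. Insulin and FOXO feedback genes had a median difference of 0.50 (percentile 100; 0.238 at a mean FPKM of 5), NF-kB genes 0.32 (percentile 100) and autophagy genes 0.17 (percentile 100), and 7 of 13, 8 of 18 and 9 of 26 of them were lower in shControl and higher in shARID1A beyond counting error. YAP/TAZ targets had 0.07 (percentile 99.7; 0.149 after centring), with 8 of 21 lower in shControl and higher in shARID1A, such as CTGF with 0.667 and 1.39 and CYR61 with 0.565 and 1.32. Ribosome biogenesis genes had -0.30 (percentile 0), with 16 of 28 higher in shControl and lower in shARID1A, such as RRS1 with 1.47 and 0.745, and heat shock genes -0.45 (percentile 0; -0.255 as the mean of the list), with 5 of 10 in that order.

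At 2-fold, the difference of the rapamycin effects was above 0 for 93 and below 0 for 43 of 10788 genes, with 24 and 27 of them under 50 fragments in every library. Of the genes called in single genotypes, 3 were lower with rapamycin in shControl and higher in shARID1A and 0 the reverse, where independent lists would share 0.0275 and 0.0121, and 6 and 3 by the rule on fragments, against 0.252 and 0.254. For the difference, the rule on fragments gave 201 and 159, and simulated libraries with no difference gave 84 calls by that rule among 12851 genes and 30 by the rule on FPKM among 10772. Across genes the rapamycin changes in both genotypes had a Pearson r of -0.306 and a Spearman rho of -0.370, against a mean r of 0.00495 in 20 simulations with counting error only. Over the 7439 genes with a mean of at least 500 fragments these were -0.438 and -0.463 on log2(FPKM + 1). Mitochondrially encoded transcripts had the order of the lysosome and FOXO genes, with 9.17% and 7.96% of the fragments in shControl and 7.78% and 8.24% in shARID1A, DMSO first.

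**Figure D3:**
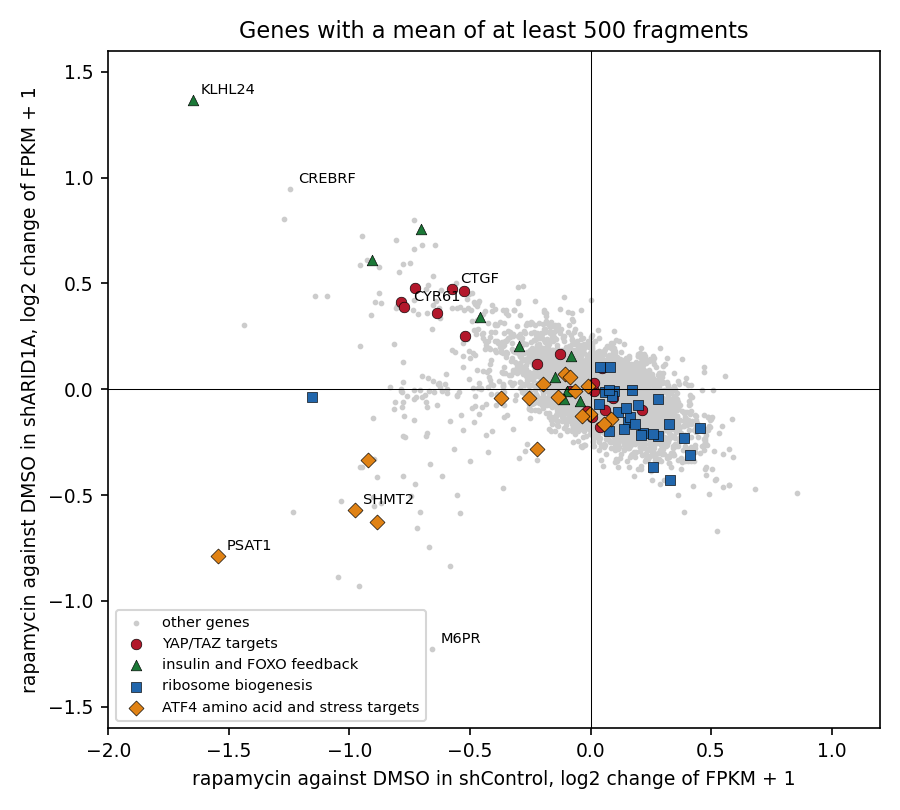
Rapamycin against DMSO in shARID1A (y, log2 change) against the same in shControl (x, log2 change), 1 library per group, with genes of the text marked. Only genes with a mean of at least 500 fragments are shown. KLHL24 lies at upper left, and PSAT1 is below 0 on both axes.

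The knockdown difference, averaged over treatments, and the rapamycin difference, averaged over genotypes, had little relation across genes. Their Pearson r was 0.106 and their Spearman rho 0.0514 across 10788 genes, against a mean r of 0.0233 (SD 0.0413) in the simulations. The covariance was 0.0030, against 0.00014 simulated. Genes low on both counts included PSAT1, at 0.456 and 0.770 of shControl with DMSO and with rapamycin, EDEM1 at 0.585 and 0.607, and M6PR at 0.715 and 0.467. Sterol genes had medians of -0.17 for the knockdown and -0.06 for rapamycin (percentile 0 in both), and p53 target genes -0.25 and -0.06 (percentile 0 in both). As the mean of the list, the sterol values were -0.099 and -0.134 and the p53 value for the knockdown -0.107. In single arms, the sterol list lay at percentile 53.7 for the knockdown with rapamycin and, with medians of -0.04 and -0.03 for rapamycin in shControl and shARID1A, at 0.27 and 16.5, and the p53 list lay at 14.3 for the knockdown with rapamycin and at 46.7 for rapamycin in shARID1A. NOLC1 and HABP4, both higher with the hairpin, had rapamycin ratios of 1.13 and 1.07 in shControl and 0.912 and 1.01 in shARID1A.

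Marker genes of other cell types were led by COL1A2 and LYZ. The 10 fibroblast and stellate genes summed to 240, 248, 209 and 206 fpm in the order shControl with DMSO, shControl with rapamycin, shARID1A with DMSO and shARID1A with rapamycin, of which COL1A2 gave a mean of 130 fpm. The 14 leucocyte genes summed to 964, 994, 874 and 807 fpm, of which LYZ gave a mean of 905 fpm, and LYZ had shARID1A to shControl ratios of 0.906 and 0.812. Endothelial genes summed to 4.52, 3.43, 3.72 and 4.62 fpm, and squamous epithelial genes to 7.87, 7.23, 9.52 and 8.81 fpm. Erythroid genes stood at 0.0932, 0, 0.186 and 0.0873 fpm. These lists had under 5 measured members and were given no percentile. Replication histone genes took 0.0237%, 0.0262%, 0.0292% and 0.0310% of the fragments, with 6 of 13 higher and 0 lower in shARID1A in both treatments, and no small non-coding RNA gene was among the listed genes.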

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

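The tests of exchanged labels, of FPKM lengths and of depth were chosen after their results were seen, and the tests of GC content and length before. Bootstrap intervals of list medians below do not cover variation between libraries or cultures. With 1 library per group, none of the differences between genotypes below was tested against replicates. Each was picked out because the rapamycin change went 1 way in shControl and the opposite way in shARID1A.

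Among the genes of the named-gene rule, KLHL24 had a difference of the rapamycin effects of 3.17 (3.03 to 3.30) on the log2 scale of fragments, with ratios of 0.3 in shControl and 2.7 in shARID1A. RHEBL1 had 2.79 (2.04 to 3.53), CREBRF 2.37 (2.14 to 2.61), FBXO32 2.23 (1.39 to 3.06) and ZNF114 2.20 (1.71 to 2.68). CHAC1 had the opposite sign, at -3.07 (-3.88 to -2.26). FBXO32, RHEBL1 and CHAC1 rest on few fragments, between 25 and 134 per library.

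Among the gene lists, the median difference of the rapamycin effects was 0.50 for insulin and FOXO feedback (0.238 at a mean FPKM of 5), 0.32 for NF-kB inflammatory genes, 0.32 for mitochondrially encoded genes, 0.23 for lysosome and 0.17 for autophagy. It was 0.067 for YAP/TAZ targets (0.149 after centring, 0.320 as the mean of the list) and 0.053 for mesenchymal and extracellular matrix genes, the last of which was -0.023 on recovered fragments. It was -0.30 for ribosome biogenesis and -0.45 for heat shock (-0.255 as the mean of the list).

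The opposite rapamycin responses have technical explanations to weigh beside a biological one. If the treatment labels were exchanged within 1 of the 2 pairs, a response shared by the genotypes would appear in opposite directions, but the ATF4 targets had medians of -0.17 in shControl (bootstrap interval -0.370 to -0.037) and -0.13 in shARID1A (-0.335 to -0.0074), each below all matched random lists. After centring the shARID1A interval reached above 0 (-0.310 to 0.018) but stayed far below the mirror image of shControl (-0.23) that an exchange would give. For this list, that argues against the exchange as the whole cause. Other values go with an exchange. By Pearson r on log2(FPKM + 1), shControl with rapamycin was closer to shARID1A with DMSO (0.9926) than to shARID1A with rapamycin (0.9907). Likewise, shControl with DMSO was slightly closer to shARID1A with rapamycin (0.9913) than to shARID1A with DMSO (0.9909). These r values are taken across genes on FPKM levels, so that they depend on the lengths in the FPKM. A bias of GC content and length is argued against, since removing trends in GC, length and level left the correlation at -0.452 over 7426 genes (-0.447 before, over 7439, Pearson on log2 of fragments), with 2.93% of the variance removed. A genotype that alters the response and a difference between cultures in density, medium or timing, which 1 library per group confounds with the groups, stay open and were not tested, as does an exchange together with a response that differs by genotype.

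The lower glycolysis and hypoxia genes in shARID1A appeared in 2 pairs of libraries, with a median log2 change of -0.43 over both, and removing trends in GC, length and level left the median of the 19 members with at least 500 fragments at -0.43 (-0.41 before), which argues against those trends as the whole cause. An effect in proportion to log2 depth, with depths 1.5-fold apart with DMSO and 1.25-fold with rapamycin, would put the difference of the rapamycin effects at 0.351. Its median over the 22 members was -0.12 (bootstrap interval -0.256 to 0.116). This argues against such an effect in these libraries only as far as that interval goes, since variation between cultures is not in it. The rapamycin change was 0.094 in shControl, where depth would also raise it, and -0.062 in shARID1A, where depth would raise it more, and other effects of depth stay open because both shARID1A libraries are deeper than both shControl libraries. An effect of the hairpin, an effect of other targets of the hairpin and a difference in the density or oxygen supply of the cultures stay open, and the difference in ARID1A itself (ratios of 0.890 with DMSO and 0.695 with rapamycin) does not decide between them. The data thus give a hypothesis, that ARID1A depletion may lower glycolysis genes, which replicate cultures and a second hairpin would have to test.

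The FPKM levels within a library may carry lengths of other genes. The Spearman correlation of the length in the FPKM with the gene's own exonic length was -0.016 across 10868 genes, and 7.31% of genes had a length within 10% of their own. Of 656 genes with a length above 12000 bases, 79.3% had exactly the exonic length of some gene of GENCODE release 29, against 12.5% for the same lengths plus 1 base, which goes with lengths joined to names in a wrong order. Ratios of a gene between libraries are not touched by this, while the r values between whole libraries above are.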

How the results depend on the processing

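No paired analysis was possible because each group holds 1 library, so that no replicate numbers pair the samples. The additive models of genotype and treatment below have 1 residual degree of freedom. The recovered fragments, limma-voom and the genes of at least 500 fragments were alternatives chosen after seeing the data. In what follows, pairs are genes higher and lower. Of the values for whole comparisons under the alternatives, 67 stayed close to the main value and 62 moved, and of those for single genes and lists 1305 stayed, 204 moved and 5 reversed. Reversed does not cover every change of sign. Some small list medians changed sign with centring or quantile normalization and are not among the reversed. The difference of rapamycin effects of SWI/SNF subunits, for example, was -0.059 as deposited and 0.023 after centring. Leaving out mitochondrial and histone genes moved none of the 14 counts. Except where said, the cause was not tested. Settings that need counts (edgeR, DESeq2 and their scalings) were not run, since the files hold FPKM.

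For shARID1A against shControl with DMSO (27 and 51), requiring a mean FPKM of 5, which tests fewer genes, gave 33 lower. The counts were 59 and 101 with a pseudocount of 0.1, 236 and 343 with the 1.5-fold rule, 137 and 211 on recovered fragments, 20 and 70 with centring, and 20 and 64 with quantile normalization. With rapamycin (45 and 57), they were 29 and 31 with a mean of 5, 83 and 116 with the pseudocount, 230 and 349 at 1.5-fold, and 135 and 219 on fragments. Over both treatments (7 and 17), they were 11 and 38 with the pseudocount, 69 and 129 at 1.5-fold, and 21 and 63 on fragments. The additive limma model called 0 and 0 genes at an adjusted p under 0.05 (1067 and 966 at an unadjusted p under 0.05), and limma-voom 153 and 262 (1308 and 1219 unadjusted).

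For rapamycin in shControl (13 and 33), the counts were 3 and 16 with a mean of 5, 24 and 56 with the pseudocount, 57 and 176 at 1.5-fold, and 48 and 81 on fragments. In shARID1A (9 and 10), they were 15 and 16 with no filter, 4 and 2 with a mean of 5, 21 and 23 with the pseudocount, 54 and 48 at 1.5-fold, and 40 and 68 on fragments. Over both genotypes (1 and 1), centring left 0 higher, quantile normalization left 0 higher, no filter gave 3 lower, and a mean of 5 left 0 lower. The 1.5-fold rule gave 5 and 13, and fragments 0 and 3. Limma called 0 and 0 (53 and 107 unadjusted) and limma-voom 0 and 2 (35 and 103 unadjusted), the latter PPIA and PSMB5, named after their values were seen. For the difference of the rapamycin effects (93 and 43), a mean of 5 gave 17 lower and the pseudocount 78 lower, the 1.5-fold rule 287 and 287, and fragments 201 and 159. A lower pseudocount gives more weight to low FPKM and the 1.5-fold rule admits smaller changes, by construction. The fragment rule changes the filter, the prior and the interval together, and which of these moved its counts was not tested.

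ARID1A with DMSO had a log2 change of -0.17, and of -0.23 after centring. The correlation of the knockdown effect against rapamycin effect (0.106) was 0.142, 0.0662 and 0.146 under its alternatives. At a mean of 5, the median knockdown change of ATF4 targets reversed to 0.0011 and that of autophagy to 0.014, and the difference of rapamycin effects of interferon genes to -0.10. On fragments that of extracellular matrix genes reversed to -0.023, and the rapamycin change of heat shock genes, as the mean of the list, to -0.017. For the difference of rapamycin effects, insulin and FOXO genes (0.50) were at 0.238 with a mean of 5 and 0.759 as the mean of the list, YAP/TAZ targets (0.067) at 0.149 with centring and 0.320 as the mean, extracellular matrix genes (0.053) at 0.135 with centring, and heat shock genes (-0.45) at -0.255 as the mean. Taking the mean of the list also took YAP/TAZ targets under rapamycin to percentile 3.05. Depth limits the genes with under 50 fragments, whose counting intervals span several-fold.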

Other observations

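The test of proteasome genes was chosen after single genes had been seen. Gene groups not described above had small median changes, most of them inside the central 95% of matched random lists. In shARID1A against shControl, extracellular matrix genes had medians of -0.08 with DMSO (percentile 2.34) and 0.09 with rapamycin (percentile 95.4). The integrin gene ITGB1 had ratios of 0.597 and 0.585 and the crosslinking enzyme gene LOXL2 0.641 and 0.508, whereas the thrombospondin gene THBS1 had 1.28 and 1.9. Fetal liver, progenitor and biliary markers had medians of -0.03 (percentile 10.6) and -0.07 (percentile 10.8), with the osteopontin gene SPP1 at 2.03 and 1.75 against CD44 at 0.625 and 0.708 and IGF2 at 0.71 and 0.706. Interferon-stimulated genes had medians of -0.02 (percentile 11.2) and 0.07 (percentile 87.9), with OAS3 at 0.611 and 0.623 and USP18 at 1.57 and 1.24. CXCL10 was lower at 0.486 and 0.441. Wnt target genes had medians of 0.11 (percentile 68.6) and 0.05 (percentile 77.1), with the secreted inhibitor gene DKK1 at 1.86 and 1.36. G1/S and replication genes had medians of 0.14 (percentile 92.1) and 0.09 (percentile 96.9), with UNG at 1.61 and 1.57.

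Under rapamycin in shControl, some replication genes were lower while their list was not. RRM2 had a ratio of 0.557 and MCM4 0.583, against 0.996 and 0.978 in shARID1A, and the list median was 0.04 in shControl (percentile 27.8), -0.02 after centring and 0.00083 after quantile normalization. Unfolded protein response genes had medians of -0.05 with DMSO (percentile 4.72) and -0.04 with rapamycin (percentile 23.8) for shARID1A, and the chaperone gene HSPA5 had a ratio of 0.603 under rapamycin in shControl and 0.975 in shARID1A. mTOR pathway components had a median of 0.07 in shARID1A with DMSO (percentile 43.0), which was -0.0004 after centring and -0.0017 after quantile normalization, and 0.05 with rapamycin (percentile 90.9). The mTOR inhibitor gene DEPTOR had a rapamycin ratio of 1.6 in shControl and 0.978 in shARID1A. Immediate early genes had a median of 0.06 in shARID1A with rapamycin (percentile 90.1), with ETV5 at 3.8 and FOS at 0.512, and 0.04 with DMSO (percentile 28.9), which was -0.02 after centring. Under rapamycin they had medians of -0.03 in shControl (percentile 0.515) and -0.02 in shARID1A (percentile 53.05), and of -0.04 over both genotypes (percentile 0.07).

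A hypothesis arose from PSMB5, a proteasome subunit gene with a rapamycin log2 change of -0.96 in the limma-voom fit, that proteasome subunit transcripts are lower with rapamycin. It called for a median below the central 95% of matched random lists and below 0 in both genotypes, which was not met. The opposite outcome set for the test, medians above that range in both genotypes, was not met either. As a group the genes were not lower over both genotypes, though the members go both ways. The median rapamycin change of 32 proteasome genes over both genotypes was 0.038, at percentile 94.5, with 7 genes lower and 3 higher beyond counting error in both genotypes. In shControl the median was 0.078, with 9 lower and 15 higher, and in shARID1A -0.0075, with 11 lower and 3 higher. For shARID1A against shControl, the median of these genes was 0.0068 with DMSO (percentile 11.0), with 10 lower and 12 higher. With rapamycin it was -0.090 (percentile 1.63), with 16 lower and 3 higher, and 9 were lower and 3 higher in both treatments.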
